A study of Mus musculus with 32 samples.

How the data were processed

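RNA was measured in 32 libraries of E14 mouse embryonic stem cells, 2 for each of 16 groups. The groups are 2iL and 2i before withdrawal and 7 times after withdrawal in each course. Per the labels, poly(A) RNA was made into libraries read from the 3' end of transcripts (NEGEDIA Digital mRNAseq). The submitters' processing notes name bcl2fastq, STAR 2.6.0a, HTSeq and genome build mm10, and do not state the annotation release. The authors deposited 1 file of counts per library, with whole numbers of uniquely aligned reads for 31053 Ensembl genes and 5 summary lines of reads outside genes. The deposited table of CPM (counts per 1000000 counts) for the same 32 libraries was checked against the counts, and the largest difference from counts scaled to that total over genes was 4.7e-10. All results rest on the counts. Gene symbols, positions and types came from GENCODE M21, which names 30934 of the gene IDs and leaves 119 without a symbol. Between 23.4% and 55.4% of uniquely aligned reads lay outside annotated genes, and these reads, like those aligned to several places, were not used here.

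Each library was placed in its group by the labels. Replicate numbers are taken from the labels, and no pairing of libraries is stated. Depth differed, with 1122648 to 3438514 counts in 31 libraries and 7298 in 2iL 36 h replicate 2, which was kept and also left out as an alternative. The floor for a count of 0 was 3 counts, over the group where groups are compared. A fold against a group of 0 counts is given as a lower bound against that floor, and a fold against 1 to 3 counts as a ratio with its 95% counting interval (exact Clopper-Pearson).

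Tests used edgeR 4.0.16 in R 4.3.3, with TMM normalisation and filterByExpr on the groups, which left 11761 genes. The quasi-likelihood test (glmQLFit and glmQLFTest) used a single fit of all 32 libraries with a coefficient per group, which leaves 16 residual degrees of freedom. The common dispersion was 0.0215. The p-values were adjusted by Benjamini and Hochberg over all tested genes, and genes with an adjusted p under 0.05 are said to have changed. The comparisons were 2i against 2iL before withdrawal, each withdrawal time against 0 h of its course, and all 7 times of a course jointly. The difference between courses, the change in the 2iL course minus the change in the 2i course, was tested at 24, 48 and 72 h and jointly over the 6 shared times. A withdrawal time is thus compared with libraries taken before the medium change, and time in culture goes with it. Levels in CPM are normalised with the TMM factors.

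Gene lists written down before the files were opened, 24 in all with 266 genes, were tested in 8 comparisons (2i against 2iL, 12, 24 and 72 h of the 2i course, 24 and 72 h of the 2iL course, and the difference between courses at 24 and 72 h). Lists of cell states and signalling were naive pluripotency, general pluripotency, formative epiblast, DNA methylation writers, LIF and STAT3 targets, beta-catenin and TCF targets, ERK targets and feedback, the Nodal pathway, primitive streak, early neural and mesenchymal. Lists of the cell cycle and of metabolism were p53 targets, S phase entry, G2 and mitosis, glycolysis, oxidative phosphorylation, cholesterol synthesis, and ATF4 and amino acid response. Markers of other cell types were primitive endoderm, definitive endoderm, trophectoderm, germline, fibroblast and 2-cell-like cells. Some genes stand in 2 lists, so the results of these lists overlap. Dnmt3a, Dnmt3b and Dnmt3l are both formative genes and writers of DNA methylation. Klf4, Tfcp2l1 and Gbx2 are both naive genes and LIF and STAT3 targets. Lef1, T, Tdgf1, Ccnd1 and Sesn2 are shared by other lists. Camera (limma 3.58.1), which compares a list with the other genes, was run on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and p-values were adjusted over the lists of a comparison. Adjusted p-values of lists are from camera unless an estimated correlation is named. Of 184 tests camera called 74, 23 of which held with the correlation estimated from the data. The median, mean and test of a list differed in sign in 27 tests, none of them called. Fry, which asks whether a list moves to 1 side on balance, called 56. Counts of list members are given over all tested genes and adjusted over the list alone. Of 368 such counts over all tested genes 151 were 0 by edgeR, all 151 were 0 by DESeq2, and at an unadjusted p under 0.05 103 of them were 0 and the rest at most 5. DESeq2 called fewer genes than edgeR, so its counts of 0 say little about whether a changed member was missed.

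Named genes follow a rule written before the files were opened. They are members of the lists and the 10 largest rises and 10 largest falls for 2i against 2iL, 12 h of the 2i course and 72 h of each course (adjusted p under 0.05, mean log2 CPM of at least 3, replicates that do not overlap). The 10 genes with the smallest p of the joint test of the difference between courses at that level are named too. Predicted genes were counted without being named. Genes outside this rule appear only where the text says that they were chosen after their values were seen.

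The test was tried on simulated data, in which the counts of 100 genes were raised or lowered 2-fold, and those of 100 others 4-fold, in 1 group. At 72 h of the 2iL course it found 33% of 2-fold and 77% of 4-fold changes with 9 false calls, and for the difference between courses at 72 h 5% and 45% with 1 false call. At 36 h of the 2iL course, which holds the shallow library, it found 14% and 65%. DESeq2 found 14% and 54% at 72 h of the 2iL course. Of simulated lists of 15 genes camera called 3 of 3 that were raised and 0 of 20 left unchanged, with the preset and with the estimated correlation alike, and fry called 0 of 3. The simulated genes were drawn independently of each other. The simulation therefore cannot show how either correlation setting deals with genes that move together.

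Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0 with its own size factors, a fit of the libraries compared alone, replicate number as a block, a prior count of 0.5 for lists, the estimated correlation, and leaving out each library of the groups compared in turn. Added after the data were seen were fits without the shallow library, without 4 libraries that stand apart from their partners, and without Gm42418 and Gm26917, which hold ribosomal RNA sequence. Groups of 2 are too small for a search for outlying libraries within a group or for counting other splits of the libraries. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.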

Results

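Messenger RNA was profiled in E14 mouse embryonic stem cells that left the naive pluripotent state. The cells were kept in N2B27 medium with 2i or with 2iL. The 2i medium holds 3 uM CHIR99021, an inhibitor of the kinase GSK3, and 1 uM PD0325901, an inhibitor of the kinase MEK, and 2iL holds the cytokine LIF as well. All of these were then withdrawn by a change to N2B27. The 2iL course was sampled at 0, 24, 36, 48, 60, 72, 84 and 96 h and the 2i course at 0, 12, 24, 36, 48, 60, 72 and 84 h. Each time had 2 libraries, which makes 32 in all. Of these libraries 31 held 1122648 to 3438514 counts (median 1980949) over 12212 to 17215 detected genes. The floor used here, 3 counts, corresponds to 0.873 to 2.67 CPM (counts per 1000000 counts) in them. The library 2iL 36 h replicate 2, the shallow library below, held 7298 counts over 2769 genes, with a floor of 411 CPM, and means of that group are not given. The labels do not state how the replicates were obtained, so p-values measure only the spread between samples. Intervals and floors cover counting error only. Values after ± are standard errors for log2 fold changes and standard deviations for levels in CPM, each with n = 2 libraries per group. A standard error is the absolute log2 fold change over the square root of its quasi-likelihood F statistic. It thus rests on a spread pooled over all groups of the fit. A list's p from an estimated correlation is given where its call was lost with it. That correlation was estimated from all 32 libraries, the shallow one among them. More of the calls held with it when the shallow library was left out, and fewer when the 4 libraries that stand apart were. These counts are given with the processing settings.

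What LIF adds to the 2 inhibitors was asked by comparing 2i with 2iL before withdrawal. Transcripts of the LIF pathway and part of the naive network were lower in 2i. Transcripts of the formative epiblast, the state that follows naive pluripotency, were already higher. Socs3 (ENSMUSG00000053113, chromosome 11, 117966079 to 117970047, build mm10) is the feedback inhibitor of the LIF receptor. It had 67 counts in 2iL and 0 in 2i and was at least 20.7-fold lower in 2i (adjusted p = 2.3e-05). Stat3 (ENSMUSG00000004040, chromosome 11, 100885098 to 100939540), the transcription factor that LIF activates, was at 97.1 ± 1.01 CPM in 2iL and 17.3 ± 2.06 CPM in 2i (log2 fold change -2.50 ± 0.29, adjusted p = 1.4e-07). Klf4 (ENSMUSG00000003032, chromosome 4, 55527143 to 55532466), a naive transcription factor downstream of STAT3, was at 667 ± 21.3 CPM in 2iL and 112 ± 31.1 CPM in 2i (-2.56 ± 0.27).

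Of 10 tested LIF and STAT3 targets, 9 were lower in 2i and 0 higher (9 and 1 adjusted over the list alone), with a median log2 fold change of -1.83. The adjusted p of these targets was 2.0e-11, and adjusted p = 0.060 with an estimated correlation. The number of lower LIF and STAT3 targets was 6 without 2i 0 h replicate 2. Further members were Pim1, a kinase that promotes survival (-1.63 ± 0.29), and the naive transcription factor Tfcp2l1 (-1.35 ± 0.20). Of 19 naive genes, 8 were lower in 2i and 0 higher (8 and 0 adjusted over the list alone). Among these were Tcl1, a coactivator of AKT (-2.25 ± 0.25), and Tet2, an enzyme that oxidises methylated cytosine (-1.67 ± 0.30). Naive genes as a list had adjusted p = 0.0016, against adjusted p = 0.57 with an estimated correlation and 0.0545 without 2i 0 h replicate 2. The number of lower naive genes was 5 without 2iL 0 h replicate 1 and 5 without 2i 0 h replicate 2. Nanog, a gatekeeper of the naive state, did not pass the test, at 197 ± 21.7 CPM in 2iL and 178 ± 1.94 CPM in 2i (-0.15 ± 0.21, adjusted p = 0.80).

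Of 15 formative genes, 9 were higher in 2i and 0 lower (13 and 0 adjusted over the list alone; adjusted p = 3.2e-16, and 0.0542 with an estimated correlation and the libraries that stand apart left out). Their median was 2.22, or 1.49 with 2 genes that had 0 counts in a group compared set at their bound. Dnmt3l (ENSMUSG00000000730, chromosome 10, 78041947 to 78063622), the cofactor of the enzymes that set DNA methylation, was at 12.8 ± 0.520 CPM in 2iL and 161 ± 4.03 CPM in 2i (3.65 ± 0.29). The methyltransferases Dnmt3a (2.39 ± 0.22) and Dnmt3b (2.27 ± 0.22) were higher too. Of 5 writers of DNA methylation 3 were higher and 0 lower (3 and 1 adjusted over the list alone). Dnmt3a, Dnmt3b and Dnmt3l are in the formative list as well, so the writers are not a separate result. The list of writers had adjusted p = 3.5e-07, and adjusted p = 0.060 with an estimated correlation. Transcription factors of the epiblast after implantation were also higher, such as Utf1 (2.55 ± 0.23), Zic2 (2.22 ± 0.26) and Otx2 (1.37 ± 0.20). So were Wnt3, a ligand of the streak (2.16 ± 0.45), and the adhesion molecule Epcam (2.50 ± 0.19). The general pluripotency list had 5 of 11 members higher and 0 lower (7 and 1 adjusted over the list alone). It had adjusted p = 0.0016, and adjusted p = 0.57 with an estimated correlation. The number of higher members was 2 without 2iL 0 h replicate 1 and 3 without each other library compared.

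By the rule for named genes, the 10 largest rises in 2i included Car14, a carbonic anhydrase, and Sptb, a spectrin chain. Both had no count in 2iL and were at least 5.03-fold and 6.11-fold higher in 2i. Epha1, an ephrin receptor, was at least 5.39-fold higher (adjusted p = 0.0040). Its call was lost without 2iL 0 h replicate 1 (adjusted p = 0.059), 2iL 0 h replicate 2 (0.0501) or 2i 0 h replicate 1 (0.0538). Genes with 1 to 3 counts in 2iL were Vrtn, with a 2i to 2iL ratio of 26.9 (95% counting interval 7.08 to 229), Sned1, with 34.5 (95% counting interval 5.76 to 1404), and Hs6st2, with 21.5 (95% counting interval 7.03 to 107). Esrp1, a splicing factor of epithelia (4.43 ± 0.43), Gramd3 (4.36 ± 0.60) and Enox1 (4.29 ± 0.61) followed. Peg10, an imprinted gene, rose by 6.45 ± 0.41, a value of 7.60 without 2iL 0 h replicate 1 and 5.83 without 2iL 0 h replicate 2. The largest falls were 1 predicted gene, Ahnak (-5.06 ± 0.41), the small GTPase Mras (-4.92 ± 0.51), the homeobox gene Vax2 (-4.91 ± 0.48), Crxos (-4.72 ± 0.24), Rab11fip5 (-4.56 ± 0.47) and Ly75 (-4.25 ± 0.29). Bcl3, a STAT3 target, had a log2 fold change of -5.58 ± 0.37 (-4.78 without 2i 0 h replicate 1 and -6.79 without 2i 0 h replicate 2). The homeobox gene Nkx6-2 and Kbtbd11 had 2 or 3 counts in 2i. Their 2iL to 2i ratios were 70.8 (95% counting interval 23.9 to 346) and 30.2 (95% counting interval 8.02 to 254).

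In all, 994 of 11761 tested genes differed between 2i and 2iL, 474 higher and 520 lower in 2i. DESeq2 called 398, a fit of the 4 libraries alone 1984, and a fit without 4 libraries that stand apart from their partners 1640. The latter are 2iL 48 h replicate 1, 2iL 84 h replicate 2, 2iL 96 h replicate 1 and 2i 12 h replicate 2. The count was 550 and 575 without 2iL 0 h replicate 1 and 2, and 532 and 633 without 2i 0 h replicate 1 and 2.

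The first response to withdrawal was sampled at 12 h of the 2i course. Some targets of beta-catenin, which CHIR99021 stabilises, and some genes of the Nodal pathway had fallen. Part of the naive network had begun to fall, and most formative genes rose further. Lefty2 (ENSMUSG00000066652, chromosome 1, 180893108 to 180899103), the secreted inhibitor of Nodal, was at 903 ± 39.8 CPM at 0 h and 6.90 ± 1.78 CPM at 12 h (-7.06 ± 0.31, adjusted p = 8.6e-18). Nanog (ENSMUSG00000012396, chromosome 6, 122707489 to 122714633) was at 178 ± 1.94 CPM and 57.5 ± 13.5 CPM (-1.61 ± 0.24, adjusted p = 1.6e-05). Dnmt3l was at 161 ± 4.03 CPM and 824 ± 87.8 CPM (2.36 ± 0.23). Gm42418, which holds ribosomal RNA sequence, rose too (1.49 ± 0.40, adjusted p = 0.012), and Rps12, a ribosomal protein gene, fell (-1.08 ± 0.30, adjusted p = 0.014), both chosen after their values were seen. The change of Gm42418 was 1.38 (adjusted p = 0.14) without 2i 0 h replicate 1, 1.59 (adjusted p = 0.071) without 2i 0 h replicate 2 and 1.17 (adjusted p = 0.14) without 2i 12 h replicate 2, and that of Rps12 -1.06 (adjusted p = 0.095) without 2i 0 h replicate 1, -1.12 (adjusted p = 0.060) without 2i 0 h replicate 2, -1.21 (adjusted p = 0.058) without 2i 12 h replicate 1 and -0.99 (adjusted p = 0.14) without 2i 12 h replicate 2. The 10 most abundant genes held 35.5% and 43.5% of counts in the 12 h libraries and 22.3% and 24.7% at 0 h, and an effect of RNA quality on the lists was not tested.

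Of 8 genes of the Nodal pathway, 5 fell and 0 rose (5 and 0 adjusted over the list alone). The pathway had adjusted p = 1.0e-07, and adjusted p = 0.068 with an estimated correlation, and 3 members fell whichever of the 4 libraries compared was left out. Smad7, an inhibitor of the pathway, fell by 2.31 ± 0.33 on the log2 scale. Of 12 targets of beta-catenin and TCF, 4 fell and 0 rose (5 and 0 adjusted over the list alone; adjusted p = 1.8e-05, and 0.0765 with an estimated correlation and the libraries that stand apart left out), and 2 fell without 2i 12 h replicate 1. Their median was -1.38, or -1.17 with 3 genes that had 0 counts in a group compared set at their bound. Cdx2, a caudal homeobox gene, went from 46 counts to 0 and was at least 8.71-fold lower. Of 7 streak genes 2 fell and 0 rose (2 and 0 adjusted over the list alone; adjusted p = 1.6e-09).

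Of 19 naive genes, 9 fell and 2 rose at 12 h (10 and 2 adjusted over the list alone). As a list they had adjusted p = 0.015, and adjusted p = 0.66 with an estimated correlation, 0.0889 without 2i 0 h replicate 1, 0.108 without 2i 12 h replicate 2 and 0.1 without the libraries that stand apart. Klf2, a naive transcription factor, fell by 2.53 ± 0.24 on the log2 scale. Tfcp2l1 fell by 1.67 ± 0.21, and Esrrb, a naive target of GSK3 inhibition, fell by 1.39 ± 0.26. Tet2 rose (2.10 ± 0.31), and without 2i 12 h replicate 1 it was 1 gene that rose. Of 15 formative genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone), among them Otx2 (1.45 ± 0.19) and Dnmt3a (1.05 ± 0.19). Sox11, of the early neural list, rose too (1.03 ± 0.17). The formative list had adjusted p = 7.2e-11, and adjusted p = 0.056 with an estimated correlation. Of 13 ERK targets 3 rose and 3 fell (3 and 3 adjusted over the list alone), with Etv4, a transcription factor induced by ERK signalling, up by 3.10 ± 0.28. The ERK list did not pass (adjusted p = 0.17), but did without 2i 0 h replicate 1 (0.0416). Without 2i 0 h replicate 1, 2i 0 h replicate 2, 2i 12 h replicate 1 and 2i 12 h replicate 2 in turn 1, 1, 2 and 1 ERK targets rose and 0, 2, 0 and 1 fell.

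The largest rises at 12 h by the rule for named genes were Vax2 (6.46 ± 0.45), the noncoding transcript Halr1 (4.57 ± 0.42), Ahnak (4.52 ± 0.44), Zfp423 (4.39 ± 0.37) and the integrin chain Itga3 (4.06 ± 0.44). A further 4 genes had 1 or 2 counts at 0 h. Their ratios of 12 h to 0 h were 44 (95% counting interval 7.21 to 1808) for Jph4, 30.8 (95% counting interval 7.92 to 264) for Kbtbd11, 35.2 (95% counting interval 5.63 to 1460) for Wt1, a zinc finger factor, and 26.4 (95% counting interval 4.06 to 1112) for Nptxr. Spink1, with 4 counts at 12 h and 0 at 0 h, was at least 2.35-fold higher (adjusted p = 0.049). It lost its call without 2i 0 h replicate 1 (adjusted p = 0.235) or 2 (0.146), without 2i 12 h replicate 1 (0.11) or 2 (0.17), by DESeq2 (0.16) and in 4 other settings. The largest falls after Lefty2 were Tfap2c, a germline and trophoblast factor (-5.10 ± 0.34), Lefty1, a further inhibitor of Nodal (-5.04 ± 0.39, and -6.05 without 2i 12 h replicate 1), and Ap3b2 (-4.51 ± 0.41, or -3.59 without 2i 12 h replicate 1 and -6.17 without 2i 12 h replicate 2). Peg12 had 0 counts at 12 h and was at least 7.95-fold lower. With 1 to 3 counts at 12 h, the ratio of 0 h to 12 h was 43.9 (95% counting interval 14.8 to 215) for Nkx1-2 and 17 (95% counting interval 4.52 to 144) for Hs6st2. It was 26.1 (95% counting interval 4.46 to 1054) for Acot1, whose call was lost without 2i 12 h replicate 1 (adjusted p = 0.0535). Fam19a4 (at least 3.22-fold lower) and Chrna4 (at least 1.89-fold lower) had 0 counts at 12 h. They lost their calls by DESeq2 (adjusted p = 0.053 and 0.15), without 2i 0 h replicate 2 (0.078 and 0.12), without 2i 12 h replicate 1 (0.11 and 0.22) and without 2i 12 h replicate 2 (0.063 and 0.17). Chrna4 also lost its call without 2i 0 h replicate 1 (adjusted p = 0.090), without the shallow library (0.054) and without the libraries that stand apart (0.10).

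At 12 h, 1346 genes had changed, 664 up and 682 down. DESeq2 called 493 and a fit of the 2i course alone 2222. The count was 571 and 762 without 2i 0 h replicate 1 and 2, and 763 and 728 without 2i 12 h replicate 1 and 2.

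At 24 h of the 2iL course, the earliest time sampled there, most formative genes had risen and some targets of beta-catenin had fallen. Part of the naive network was still present. Dnmt3l went from 12.8 ± 0.520 CPM to 640 ± 14 CPM (5.64 ± 0.29, adjusted p = 1.0e-15). Gm42418, chosen after its values were seen, rose too (1.55 ± 0.40, adjusted p = 0.0084). The rise was 1.56 (adjusted p = 0.116) in a fit of the 2iL course alone, 1.39 (0.123) without 2iL 0 h replicate 1 and 1.68 (0.0549) without 2iL 0 h replicate 2. The 24 h libraries had 30.6% and 30.5% of counts in the 10 most abundant genes against 17.1% and 18.9% at 0 h, and an effect of RNA quality on the lists was not tested. Pou3f1 (ENSMUSG00000090125, chromosome 4, 124656807 to 124660655), a POU factor of the formative epiblast, rose by 3.66 ± 0.40 and Sox11 by 3.22 ± 0.21. Of 15 formative genes 11 rose and 0 fell (12 and 0 adjusted over the list alone; adjusted p = 4.5e-16, and 0.0667 with an estimated correlation and the libraries that stand apart left out), with 7 up without 2iL 24 h replicate 1. Axin2, a target of Wnt signalling, fell by 2.32 ± 0.49 on the log2 scale. Sp5, another such target, had a ratio of 0 h to 24 h of 65.3 (95% counting interval 17.9 to 542). Of 12 targets of beta-catenin and TCF 5 fell and 2 rose (6 and 2 adjusted over the list alone; adjusted p = 7.5e-05, and 0.0667 with an estimated correlation and the libraries that stand apart left out). Without 2iL 24 h replicate 1, 3 fell, and 0 rose whichever of the 4 libraries compared was left out. Nanog went from 197 ± 21.7 CPM to 82.7 ± 14 CPM (-1.26 ± 0.23). Tfcp2l1 (-2.50 ± 0.21) and Dppa3, a maternal factor that protects methylation (-3.27 ± 0.45), also fell. Of 19 naive genes, 8 fell and 3 rose (12 and 3 adjusted over the list alone). These numbers were 5 and 1 without 2iL 0 h replicate 1 and also without 2iL 24 h replicate 2, and 1 rose without 2iL 0 h replicate 2. The naive list had adjusted p = 0.021, and adjusted p = 0.75 with an estimated correlation, 0.0951 without 2iL 24 h replicate 1 and 0.0591 with a prior count of 0.5.

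Signalling lists moved at 24 h of the 2iL course as well. Of 13 ERK targets 5 rose and 0 fell (7 and 1 adjusted over the list alone). Spry4, a feedback inhibitor of ERK signalling, had a ratio of 24 h to 0 h of 39.1 (95% counting interval 10.1 to 334). The ERK list had adjusted p = 5.1e-05, and adjusted p = 0.20 with an estimated correlation. Without 2iL 0 h replicate 1, 2iL 0 h replicate 2, 2iL 24 h replicate 1 and 2iL 24 h replicate 2 in turn 1, 2, 1 and 3 ERK targets rose. The Nodal list had 3 of 8 members down and 0 up (4 and 1 adjusted over the list alone). Its adjusted p was 9.9e-05, and adjusted p = 0.20 with an estimated correlation. General pluripotency genes rose, with 7 of 11 up and 0 down (8 and 0 adjusted over the list alone). They had adjusted p = 8.3e-06, and adjusted p = 0.31 with an estimated correlation. At 24 h 1419 genes had changed, 654 up and 765 down. DESeq2 called 547, a fit of the 2iL course alone 904 and a fit without the libraries that stand apart 2378. The count was 706 and 779 without 2iL 0 h replicate 1 and 2, and 897 and 721 without 2iL 24 h replicate 1 and 2.

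At 24 h of the 2i course most naive genes had fallen. Nanog had gone from 178 ± 1.94 CPM to 6.86 ± 0.919 CPM (-4.70 ± 0.30, adjusted p = 6.3e-14). Esrrb fell by 4.39 ± 0.32, Nr5a2 by 3.37 ± 0.23, Klf4 by 2.99 ± 0.33 and Zfp42, also called Rex1, by 2.32 ± 0.22 on the log2 scale. Of 19 naive genes 15 fell and 0 rose (16 and 1 adjusted over the list alone). They had adjusted p = 1.8e-14 as a list, and adjusted p = 0.055 with an estimated correlation. Otx2 (ENSMUSG00000021848, chromosome 14, 48657677 to 48673819), which drives the exit from the naive state, went from 128 ± 8.47 CPM to 482 ± 34.5 CPM (1.91 ± 0.18). Fgf5, the classic marker of the formative epiblast, had a ratio of 46.4 (95% counting interval 15.6 to 227). Of 15 formative genes 11 rose and 0 fell (12 and 0 adjusted over the list alone; adjusted p = 1.8e-19). Of 8 Nodal genes 7 fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 1.8e-14). Of 12 targets of beta-catenin and TCF 6 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 8.4e-06), with Axin2 at -2.82 ± 0.43. At this time 2135 genes had changed, 1009 up and 1126 down. DESeq2 called 1027 and a fit without the libraries that stand apart 3243. The count was 1249 and 1397 without 2i 0 h replicate 1 and 2, and 1365 and 1238 without 2i 24 h replicate 1 and 2.

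Over the whole 2iL course naive genes were lost, and formative genes rose and then partly declined. The median log2 fold change of the formative list against 0 h was 4.47 at 60 h and 2.74 at 96 h. That of the general pluripotency list was 0.995 at 60 h and -0.44 at 96 h. No test compared these later times with each other. By 72 h Nanog was at 6.97 ± 0.210 CPM (-4.81 ± 0.30). Tfcp2l1 (ENSMUSG00000026380, chromosome 1, 118627945 to 118685168) fell by 7.55 ± 0.30, Klf4 by 5.92 ± 0.35, Tbx3 by 5.92 ± 0.31, Nr5a2 by 5.19 ± 0.28 and Zfp42 by 4.98 ± 0.28 on the log2 scale. In all 18 of 19 naive genes fell and 0 rose (18 and 0 adjusted over the list alone; adjusted p = 5.8e-22, and 0.0689 with an estimated correlation and the libraries that stand apart left out). All 15 formative genes rose (15 adjusted over the list alone; adjusted p = 2.5e-22), with a median of 3.76, or 3.11 with 2 genes at their bound. Pou3f1 reached 539 ± 11.5 CPM (7.89 ± 0.31) and Dnmt3b (ENSMUSG00000027478, chromosome 2, 153649450 to 153687730) 2046 ± 44.8 CPM (4.97 ± 0.23). Otx2 was at 421 ± 8.90 CPM (3.09 ± 0.20), and Utf1 rose by 3.38 ± 0.23. Of 10 LIF and STAT3 targets 8 fell and 0 rose (8 and 0 adjusted over the list alone). They had adjusted p = 4.6e-07, and adjusted p = 0.11 with an estimated correlation. Of 11 early neural genes 7 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 2.14, or 1.35 with 1 gene at its bound. The early neural list had adjusted p = 0.00021, and adjusted p = 0.11 with an estimated correlation. Sox1 (ENSMUSG00000096014, chromosome 8, 12395295 to 12400126), the first marker of the neural plate, was at 7.91 ± 3.02 CPM at 72 h and 123 ± 25.2 CPM at 96 h.

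The count of changed genes in the 2iL course was 1374 at 36 h, 3583 at 48 h, 3420 at 60 h, 3543 at 72 h (1800 up and 1743 down), 4328 at 84 h and 4840 at 96 h (2413 up and 2427 down). In all 6948 genes changed at any time. By DESeq2 these counts were 591, 1879, 1967, 2180, 2647, 3039 and 4461. The 36 h count was 61 without 2iL 36 h replicate 1, 817 and 893 without 2iL 0 h replicate 1 and 2, 915 in a fit of the 2iL course alone and 2335 without the libraries that stand apart. The 48 h count was 2195 and 2377 without 2iL 0 h replicate 1 and 2 and 2317 without 2iL 48 h replicate 1. The 60 h count was 2179 without 2iL 0 h replicate 1.

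**Figure D1:**
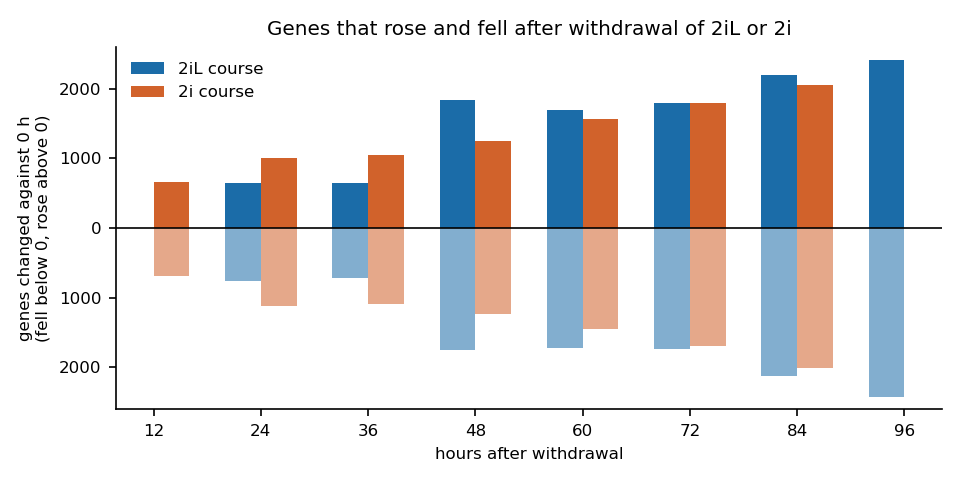
Genes that rose or fell at adjusted p under 0.05 (edgeR quasi-likelihood test, vertical axis, number of genes) against the 0 h libraries of the same course, by hours after withdrawal (horizontal axis). The counts grow from 1419 at 24 h to 4840 at 96 h in the 2iL course and from 1346 at 12 h to 4066 at 84 h in the 2i course, and 1 of the 2 libraries at 36 h of the 2iL course is the shallow one.

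In the 2i course formative genes rose early, and some had fallen again by 72 h. No test compared the formative list at 24 or 36 h with 72 h. Dnmt3b was at 315 ± 1.87 CPM at 0 h, 2060 ± 17.3 CPM at 36 h and 354 ± 15.6 CPM at 72 h. Pou3f1 was at 548 ± 30.8 CPM at 36 h and 117 ± 0.202 CPM at 72 h. Otx2 was at 482 ± 34.5 CPM at 24 h, 106 ± 0.400 CPM at 60 h and 12.4 ± 3.22 CPM at 72 h. At 72 h Otx2 (-3.38 ± 0.26), Utf1 (-3.60 ± 0.29) and Dnmt3l (-4.38 ± 0.34) lay below their level at 0 h. Of 15 formative genes 6 were up and 5 down (6 and 5 adjusted over the list alone; adjusted p = 0.27), and the median of 0.00 and the test, upward, differ in sign. Of 11 general pluripotency genes 8 fell and 2 rose (8 and 2 adjusted over the list alone), 1 rising whichever of the 4 libraries compared was left out. Pou5f1, the gene of OCT4, fell by 2.14 ± 0.42 and Sox2 fell by 2.30 ± 0.20. The general pluripotency list had adjusted p = 8.0e-07, and adjusted p = 0.28 with an estimated correlation. Of 19 naive genes 17 fell and 1 rose (18 and 1 adjusted over the list alone; adjusted p = 1.1e-17), with Zfp42 at -6.71 ± 0.38 and Esrrb at -5.95 ± 0.41. Of 8 Nodal genes 7 fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 1.1e-10).

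Early neural genes rose in the 2i course, 10 of 11 up and 0 down at 72 h (10 and 0 adjusted over the list alone; adjusted p = 2.2e-12). Their median was 4.20, or 3.61 with 1 gene at its bound. Sox1 went from 1.06 ± 0.918 CPM to 170 ± 14.5 CPM (7.39 ± 0.39, or 6.60 without 2i 0 h replicate 1 and 8.51 without 2i 0 h replicate 2). Hes5 (ENSMUSG00000048001, chromosome 4, 154960923 to 154962371), a target of Notch in neural progenitors, was at 77.5 ± 2.99 CPM, a ratio of 326 (95% counting interval 58 to 12943). At 84 h Hes5 was at 269 ± 62.1 CPM. Sall2 (4.86 ± 0.28), Sox11 (3.61 ± 0.18), Cdh2, the neural cadherin (3.51 ± 0.36), and the cyclin Ccnd2 (3.58 ± 0.20) rose too. The plot of marker levels shows these courses for 12 genes.

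**Figure D2:**
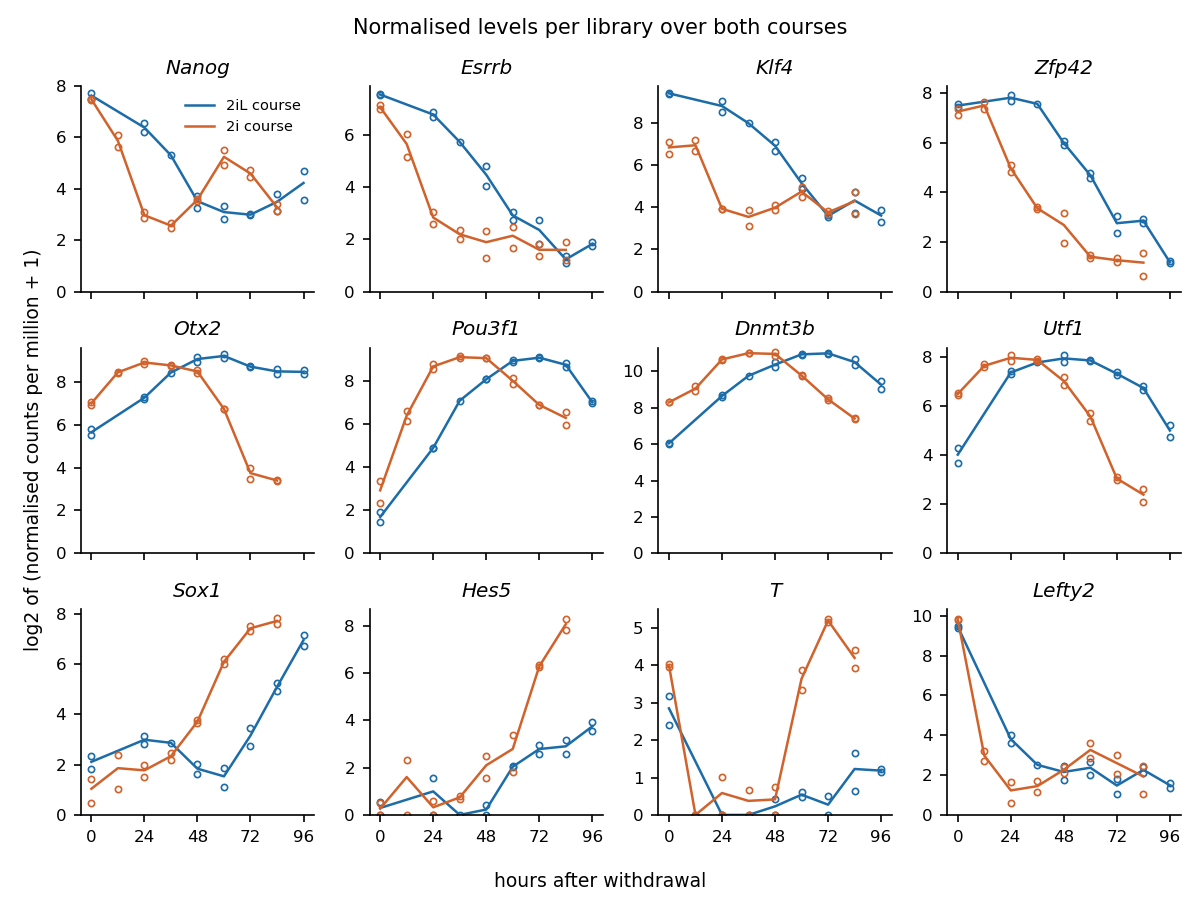
Levels of 12 marker genes, as log2 of CPM plus 1 (vertical axes), by hours after withdrawal (horizontal axes) in the 2iL and the 2i course; points are libraries, lines join the means, and the shallow library is left out. At 24 h Nanog is at 6.86 ± 0.919 CPM in the 2i course and 82.7 ± 14 CPM in the 2iL course. In the 2i course Sox1 reaches 170 ± 14.5 CPM at 72 h, where it is at 7.91 ± 3.02 CPM in the 2iL course.

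The count of changed genes in the 2i course was 2144 at 36 h, 2487 at 48 h, 3011 at 60 h, 3490 at 72 h (1797 up and 1693 down) and 4066 at 84 h (2053 up and 2013 down). In all 6440 genes changed at any time. By DESeq2 these counts were 1135, 1428, 1693, 2076, 2438 and 4296. Without 2i 0 h replicate 1 those from 36 to 84 h were 1291, 1555, 1753, 2101 and 2582. The 36 h count was 1252 and 1419 without 2i 36 h replicate 1 and 2, and the 48 h count was 1548 without 2i 48 h replicate 2. The 60 h count was 1977 without 2i 60 h replicate 1, and the 72 h count was 2266 without 2i 72 h replicate 1.

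Among the largest rises at 72 h of the 2iL course by the rule for named genes, 9 of 10 genes had no count at 0 h. Car14 was at least 131-fold higher, Fgf5 59.3-fold, Fam131b 42.4-fold, Cnn1, a calponin of contractile cells, 40.3-fold and Epha1 35.3-fold. The noncoding Miat was at least 35-fold higher, Gdap1l1 33.2-fold, Krt18, a keratin of simple epithelia, 29.3-fold and Prph, a neuronal filament protein, 25.8-fold. Btbd17 had a ratio of 372 (95% counting interval 103 to 3081). The largest falls were Vax2, at least 53.8-fold lower, Tfcp2l1 (-7.55 ± 0.30), Tcl1 (-7.15 ± 0.37), 1 predicted gene and Lefty2 (-8.51 ± 0.34, or -9.30 without 2iL 72 h replicate 1). The ratio of 0 h to 72 h was 1457 (95% counting interval 261 to 57600) for Crxos, 210 (95% counting interval 57.7 to 1736) for Jam2, a junction protein, and 237 (95% counting interval 42.1 to 9395) for Myh13. It was 230 (95% counting interval 41 to 9134) for Gprc5a and 168 (95% counting interval 46.2 to 1393) for Trpm1.

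The largest rises at 72 h of the 2i course included Mn1, without a count at 0 h and at least 51.4-fold higher, Irx5 (at least 31.8-fold), Stmn4 (at least 20.6-fold) and Miat (at least 19.6-fold). Hes5 and Sox1 were among them. Irx3, a patterning factor of the neural tube, rose by 6.58 ± 0.39 (5.95 without 2i 0 h replicate 1 and 7.37 without 2i 0 h replicate 2). The ratio was 292 (95% counting interval 51.9 to 11608) for Frzb, a secreted Wnt antagonist, 132 (95% counting interval 44.8 to 645) for Fignl2 and 116 (95% counting interval 31.6 to 967) for Btbd17. The largest falls included 7 named genes without a count at 72 h. These were Myh13 (at least 60.3-fold lower), Dppa3 (42.6-fold), Triml1 (39-fold), Phf11d (28.1-fold), Mymx (17.2-fold), Capn3 (14.7-fold) and Zfp981 (13.4-fold). Mylpf, a muscle myosin light chain, had a ratio of 0 h to 72 h of 233 (95% counting interval 64.4 to 1931), and 2 of the 10 were predicted genes.

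Metabolic genes moved at some times after withdrawal. Of 17 glycolysis genes 11 fell and 0 rose at 24 h of the 2iL course (14 and 0 adjusted over the list alone). Among them were Tpi1 (-1.74 ± 0.23), the glucose transporter Slc2a3 (-1.74 ± 0.21) and Ldha, which makes lactate (-1.24 ± 0.18). The glycolysis list had adjusted p = 5.1e-05, and adjusted p = 0.35 with an estimated correlation. Its count was 7 without 2iL 24 h replicate 1 and 5 without 2iL 24 h replicate 2. In this comparison and at 12 h of the 2i course Gm42418 rose and the 10 most abundant genes held more of the counts than at 0 h, and an effect of RNA quality on the glycolysis list was tested at neither time. At 12 h of the 2i course 6 glycolysis genes fell and 0 rose (9 and 0 adjusted over the list alone). The list then had adjusted p = 0.015, and adjusted p = 0.66 with an estimated correlation, 0.0738 without 2i 0 h replicate 1, 0.0602 without 2i 12 h replicate 2 and 0.0584 without the libraries that stand apart. The members that fell were 3 without 2i 0 h replicate 1, 4 without 2i 0 h replicate 2, 3 without 2i 12 h replicate 1 and 2 without 2i 12 h replicate 2. Glycolysis genes also fell at 24 h of the 2i course, 5 down and 1 up (6 and 1 adjusted over the list alone), and at 72 h, 9 down and 1 up (11 and 1 adjusted over the list alone), with 5 down without 2i 0 h replicate 1. There the list had adjusted p = 0.026 and 0.0022, and adjusted p = 0.50 and 0.46 with an estimated correlation, and the 24 h call was lost without 2i 0 h replicate 1 (0.128). In the 2iL course 3 rose and 5 fell at 72 h (3 and 5 adjusted over the list alone). There glycolysis did not pass (adjusted p = 0.41), and its median of 0.12 and the test, downward, differed in sign. At 24 and 72 h of the 2i course Gm42418 did not pass the test (-0.07 ± 0.39 and -0.30 ± 0.39). Of 16 genes of cholesterol synthesis 10 rose and 0 fell at 24 h of the 2i course (15 and 0 adjusted over the list alone), such as Hmgcs1 (1.18 ± 0.23) and Insig1 (1.27 ± 0.27). Cholesterol synthesis had adjusted p = 7.3e-06, and adjusted p = 0.17 with an estimated correlation. At 72 h of the 2iL course 10 of its genes rose and 0 fell (11 and 0 adjusted over the list alone). There it had adjusted p = 0.0027, and adjusted p = 0.39 with an estimated correlation. It did not pass at 24 h of the 2iL course (adjusted p = 0.113) or at 12 and 72 h of the 2i course (0.133 and 0.111), but did at the first without 2iL 24 h replicate 2 (0.0174) and at the others without the shallow library (0.0196 and 0.0285).

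Of 19 genes of oxidative phosphorylation 10 fell and 0 rose at 72 h of the 2i course (13 and 0 adjusted over the list alone). They had adjusted p = 0.0041, and adjusted p = 0.61 with an estimated correlation. The number that fell was 6 without 2i 0 h replicate 1 and 5 without 2i 72 h replicate 1. The ATF4 and amino acid response list had 6 of 11 members up and 1 down at 24 h of the 2i course (6 and 1 adjusted over the list alone). It had adjusted p = 0.00053, and adjusted p = 0.25 with an estimated correlation. Of its members 3 rose without 2i 0 h replicate 1, 4 without 2i 0 h replicate 2 and 2 without 2i 24 h replicate 2, and 0 fell whichever of the 4 libraries was left out. The lists of S phase entry, of G2 and mitosis and of p53 targets passed in none of the 8 comparisons with all libraries. Without the shallow library S phase entry passed upward at 24 h of the 2iL course (adjusted p = 0.0262, and 0.127 with an estimated correlation) and at 12 h of the 2i course (0.0469, and 0.156 with it). Targets of p53 then passed downward at 12 h of the 2i course (0.0167, and 0.0399 with it). S phase entry also passed at 24 h of the 2iL course with no filter on low counts (0.0243). At 72 h of the 2i course 6 of 13 p53 targets rose and 2 fell (6 and 3 adjusted over the list alone; adjusted p = 0.69), with 1 down without 2i 0 h replicate 2 or 2i 72 h replicate 2. There 0 of 9 mitotic genes rose and 1 fell (0 and 1 adjusted over the list alone; adjusted p = 0.39), with 0 down without 2i 0 h replicate 1 or 2i 72 h replicate 1. Of 12 S phase genes 1 rose and 0 fell (1 and 0 adjusted over the list alone; adjusted p = 0.81).

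Markers of cell types other than the epiblast were few among the tested genes. At 72 h of the 2i course 5 of 6 tested primitive endoderm markers rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 0.0042). Without 2i 0 h replicate 1, and also without 2i 72 h replicate 1, 3 of them rose. In the same comparison 4 of 5 fibroblast markers rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.00049). This count was 1 without 2i 0 h replicate 1 and 2 without 2i 72 h replicate 1. Of 6 germline markers 3 fell and 0 rose (3 and 0 adjusted over the list alone), 2 without 2i 72 h replicate 1. The germline list had adjusted p = 0.0086, and adjusted p = 0.31 with an estimated correlation. Of 5 trophectoderm markers 2 fell and 1 rose at 24 h of the 2i course (2 and 1 adjusted over the list alone). Trophectoderm had adjusted p = 0.026, and adjusted p = 0.11 with an estimated correlation, 0.0663 without 2i 0 h replicate 2, 0.0785 with no filter on low counts and 0.167 without the shallow library. The 3 definitive endoderm markers passed in no comparison as a list with all libraries. They did before withdrawal (adjusted p = 0.00884) and in the difference between courses at 24 h (0.044) without 2iL 0 h replicate 2, and in that difference at 72 h without 2iL 0 h replicate 1 (0.0151). At 72 h of the 2i course 2 of them were up, 1 whichever of the 4 libraries compared was left out (adjusted p = 0.14). Of 7 mesenchymal genes 4 rose and 1 fell there (4 and 1 adjusted over the list alone; adjusted p = 0.28), with 2 up without 2i 0 h replicate 1. None of the 2-cell-like markers passed the filter on low counts.

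Before withdrawal 3 lists of other cell types passed upward in 2i against 2iL. Of 7 streak genes 2 were higher in 2i and 1 lower (4 and 1 adjusted over the list alone). The streak list had adjusted p = 0.0013, and adjusted p = 0.070 with an estimated correlation, and 1 member was higher without 2iL 0 h replicate 1, 2iL 0 h replicate 2 or 2i 0 h replicate 2. Of 6 germline markers 2 were higher and 2 lower (4 and 2 adjusted over the list alone). Germline had adjusted p = 0.033, and adjusted p = 0.52 with an estimated correlation, 0.0746 without 2i 0 h replicate 2, 0.0845 with no filter on low counts, 0.0818 with a prior count of 0.5 and 0.113 without the shallow library. Of its members 1 was lower whichever of the 4 libraries compared was left out, and 1 was higher without 2iL 0 h replicate 1, 2iL 0 h replicate 2 or 2i 0 h replicate 2. Of 5 trophectoderm markers 0 were higher and 0 lower (2 and 0 adjusted over the list alone). The trophectoderm list had adjusted p = 0.0499, and adjusted p = 0.19 with an estimated correlation, 0.25 without 2iL 0 h replicate 2, 0.206 without 2i 0 h replicate 2, 0.195 without the shallow library and 0.0728 with a prior count of 0.5.

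Writers of DNA methylation rose at 12 and 24 h of the 2i course and at 24 and 72 h of the 2iL course, but not at 72 h of the 2i course. Of 5 tested, 4 rose and 0 fell at 12 h of the 2i course (5 and 0 adjusted over the list alone) and 3 and 0 at 24 h (4 and 0). At 24 h of the 2iL course 3 rose and 0 fell (3 and 0), and at 72 h 3 rose and 1 fell (3 and 1). In this order adjusted p was 0.00034, 3.1e-05, 1.7e-07 and 0.00023, and with an estimated correlation 0.20, 0.098, 0.048 and 0.13. At 24 h of the 2iL course it was 0.107 with that correlation and the libraries that stand apart left out. At 12 h 2 rose without 2i 0 h replicate 1, 2i 0 h replicate 2 or 2i 12 h replicate 1, and at 72 h of the 2iL course 0 fell without 2iL 0 h replicate 1 or 2iL 72 h replicate 1. In the 2i course 0 rose and 2 fell at 72 h (0 and 2 adjusted over the list alone), with 1 down without 2i 0 h replicate 1, 2i 72 h replicate 1 or 2i 72 h replicate 2 and a median of -0.44. The list then did not pass (adjusted p = 0.066), but passed downward with no filter on low counts (0.0204), with a prior count of 0.5 (0.0484) and without the shallow library (0.0386, and 0.123 with an estimated correlation). At 84 h 0 writers rose and 3 fell. Dnmt3a, Dnmt3b and Dnmt3l are formative genes as well, so these 2 lists are not separate results.

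ERK targets rose at 72 h of the 2iL course, 5 of 13 up and 0 down (6 and 0 adjusted over the list alone), and at 24 h of the 2i course, 4 up and 1 down (6 and 2). They had adjusted p = 0.010 and 0.0089, and adjusted p = 0.39 and 0.33 with an estimated correlation. The call in the 2i course was lost without 2i 0 h replicate 2 (0.0623), where 2 fell, and 0 fell there without 2i 0 h replicate 1 or 2i 24 h replicate 1. At that time 3 of 10 LIF and STAT3 targets fell and 0 rose (4 and 0 adjusted over the list alone), 2 whichever of the 4 libraries compared was left out. Those targets had adjusted p = 0.0057, and adjusted p = 0.33 with an estimated correlation. At 72 h of the 2iL course 6 of 12 targets of beta-catenin and TCF fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 0.00059, and 0.0689 with an estimated correlation and the libraries that stand apart left out). Of 8 Nodal genes 6 fell and 1 rose (6 and 1; adjusted p = 1.4e-08, and 0.0842 with that correlation and the same libraries left out). Streak genes fell at 24 h of the 2i course, 2 of 7 down and 0 up (4 and 0 adjusted over the list alone; adjusted p = 1.7e-07). In the 2iL course 3 fell and 0 rose at 24 h (3 and 0 adjusted over the list alone) and 2 and 0 at 72 h (2 and 0). There the streak list had adjusted p = 0.0025 and 0.043, and adjusted p = 0.125 and 0.23 with an estimated correlation. At 24 h it had 0.0547 without the shallow library, with 0 down without 2iL 24 h replicate 1 and 1 without 2iL 24 h replicate 2. At 72 h it had 0.101 without 2iL 72 h replicate 2, 0.0884 with no filter on low counts and 0.193 without the shallow library.

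**Figure D3:**
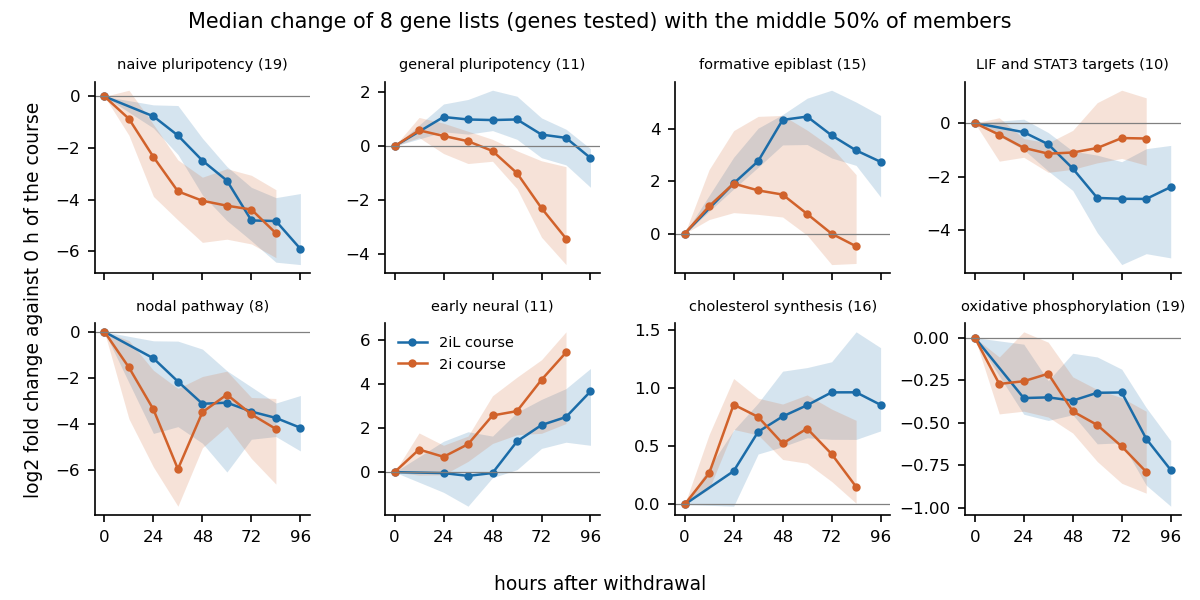
Median log2 fold change (vertical axes) of the tested members of 8 gene lists against the 0 h libraries of the same course, by hours after withdrawal (horizontal axes), with bands for the middle 50% of members. The formative list has a median of 3.76 at 72 h of the 2iL course, and the early neural list of 4.20 at 72 h of the 2i course.

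Whether LIF before withdrawal changed the response was asked by testing, at each shared time, the change in the 2iL course minus the change in the 2i course. Each change is taken from the course's own 0 h, so a gap between 2i and 2iL before withdrawal is part of every such difference. At 24 h part of the naive genes had the more negative change in the 2i course. The difference was 3.44 ± 0.38 for Nanog (adjusted p = 2.4e-07), 3.61 ± 0.40 for Esrrb, 2.87 ± 0.30 for Nr5a2 and 2.63 ± 0.29 for Zfp42. Of 19 naive genes 10 were higher in this difference and 0 lower (13 and 0 adjusted over the list alone). They had adjusted p = 2.5e-10, and adjusted p = 0.22 with an estimated correlation. At 72 h the change of most formative genes was the more positive in the 2iL course. The difference of changes was 6.47 ± 0.32 for Otx2 (adjusted p = 4.4e-16), 6.98 ± 0.37 for Utf1, 7.48 ± 0.45 for Dnmt3l and 4.80 ± 0.30 for Dnmt3b. Of these Otx2 stood at 421 ± 8.90 CPM in the 2iL course and 12.4 ± 3.22 CPM in the 2i course at 72 h, and Dnmt3l at 110 ± 4.27 CPM and 7.66 ± 0.0899 CPM. At 0 h both were higher in 2i, which widens the difference of changes (1.37 ± 0.20 and 3.65 ± 0.29). Levels of the courses at the same hour were not compared by list. Of 15 formative genes 12 were higher and 0 lower (12 and 0 adjusted over the list alone; adjusted p = 1.5e-21). Of 10 LIF and STAT3 targets 8 were lower and 0 higher (9 and 1 adjusted over the list alone), 5 without 2i 72 h replicate 2. Those targets had adjusted p = 1.1e-06, and adjusted p = 0.10 with an estimated correlation. Since 9 of them were lower in 2i at 0 h (median -1.83), a larger fall from a higher start in 2iL gives this result as well. Of 11 general pluripotency genes 7 were higher and 1 lower (8 and 1 adjusted over the list alone), with 4 higher without 2iL 0 h replicate 1, without 2i 0 h replicate 1 or without 2i 72 h replicate 1 and 0 lower without 2iL 72 h replicate 1. General pluripotency had adjusted p = 2.3e-09, and adjusted p = 0.10 with an estimated correlation. At 72 h 0 of 19 naive genes were higher and 7 lower (4 and 7 adjusted over the list alone). For the naive list the median of 0.03 and the test, downward, differed in sign (adjusted p = 0.21).

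Genes whose response differed between courses numbered 2796 over the 6 shared times, 378 at 24 h (223 up and 155 down), 1123 at 48 h (662 and 461) and 1169 at 72 h (628 and 541). By DESeq2 these counts were 1395, 141, 375 and 512. Without the libraries that stand apart 800 passed at 24 h and 2061 at 72 h. The 24 h count was 205 and 243 without 2iL 0 h replicate 1 and 2, 227 without 2iL 24 h replicate 2, 218 and 248 without 2i 0 h replicate 1 and 2, and 237 and 225 without 2i 24 h replicate 1 and 2. The 48 h count was 617 and 722 without 2iL 0 h replicate 1 and 2, 637 without 2i 0 h replicate 1, and 642 and 699 without 2i 48 h replicate 1 and 2. The 72 h count was 757 without 2iL 0 h replicate 1, 739 without 2i 0 h replicate 1 and 735 without 2i 72 h replicate 1.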

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

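The tests of the match between courses, which leave out 96 h, and the tests without the shallow library and without the 4 libraries that stand apart, were chosen after the results were seen. A test of the difference between the courses singled out 2796 genes over the 6 shared times, 378 at 24 h, 1123 at 48 h and 1169 at 72 h. The 10 genes with the smallest joint p are given with their difference at 72 h in log2 units, the change in the 2iL course minus that in the 2i course, which holds any gap at 0 h as well. They were Otx2 (6.47 ± 0.32), Utf1 (6.98 ± 0.37), Dnmt3l (7.48 ± 0.45), the junction protein gene Cgnl1 (6.43 ± 0.39) and Dnmt3b (4.80 ± 0.30). The others were Epcam (4.54 ± 0.25), Emb (4.42 ± 0.31), Dnmt3a (4.41 ± 0.29), Pou3f1 (3.67 ± 0.52, and 3.05 without 2i 0 h replicate 2) and Epha4 (-3.65 ± 0.32). Reads outside annotated genes, not used in any comparison, were a median of 37.4% of uniquely aligned reads.

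At 24 h the difference between courses passed for 8 lists. Adjusted p was 2.5e-10 for naive pluripotency, 1.2e-07 for the Nodal pathway, 7.8e-05 for general pluripotency and 0.00056 for ATF4 and amino acid response. It was 0.011 for cholesterol synthesis, 0.013 for primitive streak, 0.013 for trophectoderm and 0.0498 for formative epiblast. With an estimated correlation these were, in the same order, adjusted p = 0.22, 0.18, 0.37, 0.29, 0.56, 0.23, 0.18 and 0.66. Cholesterol synthesis lost its call without 2iL 24 h replicate 2 (adjusted p = 0.112) or 2i 0 h replicate 2 (0.0555). Primitive streak lost its call without 2iL 24 h replicate 1 (0.0848), 2i 0 h replicate 2 (0.0555), 2i 24 h replicate 2 (0.0632) or the shallow library (0.0839). Trophectoderm lost its call without 2iL 24 h replicate 1 (0.257), 2i 0 h replicate 2 (0.058) or the shallow library (0.0988), and with no filter on low counts (0.074). Formative epiblast lost its call without 2iL 24 h replicate 1 (0.0749) or 2 (0.114), 2i 0 h replicate 2 (0.0555), 2i 24 h replicate 1 (0.0837), the shallow library (0.514) or the libraries that stand apart (0.0726). The formative call was also lost with RLE size factors (0.0557), replicate number as a block (0.0641) and a prior count of 0.5 (0.119).

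At 72 h 11 lists passed. Adjusted p was 1.5e-21 for formative epiblast, 2.3e-09 for DNA methylation writers, 2.3e-09 for general pluripotency, 1.1e-06 for LIF and STAT3 targets, 2.2e-05 for primitive streak and 5.8e-05 for beta-catenin and TCF targets. It was 0.00082 for early neural, 0.00082 for germline, 0.014 for mesenchymal, 0.033 for fibroblast and 0.033 for glycolysis. With an estimated correlation these were, in the same order, adjusted p = 0.011, 0.017, 0.10, 0.10, 0.017, 0.011, 0.10, 0.10, 0.052, 0.099 and 0.62. With that correlation DNA methylation writers had 0.0612 without the libraries that stand apart and primitive streak 0.0646 without the shallow library. Without 2i 0 h replicate 1 the calls of glycolysis (adjusted p = 0.0787) and mesenchymal genes (0.0609) were lost. Fibroblast markers lost their call without 2iL 0 h replicate 1 (0.159), 2iL 72 h replicate 1 (0.0599), 2i 0 h replicate 1 (0.114), 2i 72 h replicate 2 (0.0521) or the shallow library (0.129). The fibroblast call was also lost with no filter on low counts (0.138) and with a prior count of 0.5 (0.0659).

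The 2iL course trailed the 2i course. Across 11761 genes all 6 withdrawal times of the 2iL course from 24 to 84 h correlated best with an earlier time of the 2i course, 12 h earlier at 24 h and 24 h earlier at the others. In time order the best correlations were 0.588, 0.552, 0.564, 0.553, 0.617 and 0.596, against 0.325, 0.066, -0.277, -0.242, 0.219 and 0.423 at the same hours. The 96 h time could only match an earlier one and was left out of this count. It matched 84 h best (0.661), 12 h earlier and not 24 h. Both 24 and 36 h matched 12 h of the 2i course. The 10 most abundant genes held 35.5% and 43.5% of counts in those 12 h libraries. They held 30.6% and 30.5% at 24 h of the 2iL course and 21.6% in the deep library at 36 h. An effect of RNA quality on these matches was not tested. At a lag of 24 h 95, 294, 34, 10, 93 and 588 genes differed at 36, 48, 60, 72, 84 and 96 h of the 2iL course (218, 265, 139, 42, 92 and 511 without the libraries that stand apart), and with single libraries left out 43 to 66, 57 to 1044, 5 to 15, 4 to 6, 28 to 613 and 169 to 1118, where 1044, 613 and 1118 were without 2iL 48 h replicate 2, 2iL 84 h replicate 1 and 2iL 96 h replicate 2. At the same hours from 36 to 84 h 900, 2143, 1988, 1468 and 1718 genes differed (1430, 1858, 3076, 2397 and 1311 without the libraries that stand apart, and 60 to 544, 1058 to 2602, 1021 to 1162, 668 to 934 and 793 to 2128 with single libraries left out, the 60 without 2iL 36 h replicate 1). A difference in depth as the whole cause is argued against by libraries thinned to 1 depth, where again 6 of 6 times matched earlier ones, and the libraries that stand apart by a fit without them, also 6 of 6, but a later passage through the same states with LIF before withdrawal and any other difference between the cultures, such as a shift in plating, stay open, since the count of 6 is the pattern itself and both go with the course.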

How the results depend on the processing

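The settings without the shallow library, without the 4 libraries that stand apart from their partners and without Gm42418 and Gm26917 were added after the data were seen. The other settings, the 24 gene lists, the comparisons described with the tests at the start and the rule for named genes were fixed before the data were examined. The match between courses, the comparisons of the courses at a lag of 24 h and at the same hours, and 72 against 36 h of the 2i course were not among these. Of 180 results for named genes, 170 kept their direction and their side of the threshold in every setting run, and 1 turned its direction. This was Gm42418 at 24 h of the 2i course, which did not pass the test in any setting (-0.46 to 0.25 with single libraries left out, where 0.05 was without 2i 0 h replicate 2 and 0.25 without 2i 24 h replicate 2). Among lists, beta-catenin and TCF targets at 72 h of the 2i course turned without passing, with adjusted p = 0.865 with no filter on low counts and 0.723 to 0.989 with single libraries left out (turned without 2i 0 h replicate 2, 0.989, and 2i 72 h replicate 2, 0.986). Calls lost among the genes were 4 by DESeq2, 1 in a fit of the libraries compared alone, 1 with no filter on low counts, 1 with replicate number as a block, 2 without the shallow library, 2 without the libraries that stand apart and 24 with single libraries left out. RLE size factors, no filter on low counts, replicate number as a block, leaving out the shallow library and leaving out Gm42418 and Gm26917 kept every count of changed genes within 1.5 times its value. DESeq2 gave lower counts, with 398 at 0 h (2i against 2iL), 547, 591, 1879, 1967, 2180, 2647 and 3039 from 24 to 96 h of the 2iL course and 4461 at any of them. It gave 493, 1027, 1135, 1428, 1693, 2076 and 2438 from 12 to 84 h of the 2i course, and 141, 375 and 512 for the difference between courses at 24, 48 and 72 h and 1395 jointly. A fit of the libraries compared alone gave 1984 at 0 h, 904 and 915 at 24 and 36 h of the 2iL course and 2222 at 12 h of the 2i course. Without the libraries that stand apart the counts were 1640 at 0 h, 2378 and 2335 at 24 and 36 h of the 2iL course, 3243 at 24 h of the 2i course, and 800 and 2061 for the difference at 24 and 72 h. With single libraries left out in turn the count was 532 to 633 at 0 h. In the 2iL course it was 706 to 897 at 24 h, 61 to 1353 at 36 h, 2195 to 3792 at 48 h and 2179 to 2442 at 60 h. In the 2i course it was 571 to 763 at 12 h, 1238 to 1397 at 24 h, 1252 to 1527 at 36 h, 1548 to 1961 at 48 h, 1753 to 2387 at 60 h, 2101 to 2886 at 72 h and 2582 to 3439 at 84 h. For the difference between courses it was 205 to 280 at 24 h, 617 to 1669 at 48 h and 735 to 987 at 72 h. Such a fit leaves a group with 1 library, which is assumed to vary like the other groups. For the settings that moved a count the cause was not tested. Of the 74 calls of lists by camera 23 held with an estimated correlation, 52 with it when the shallow library was left out as well, and 14 with it when the libraries that stand apart were left out. With camera itself leaving out the shallow library gave 9 further calls and lost 9. Fry called 56, 47 of them among those of camera. Of 217 counts of list members above 0, DESeq2 lowered 81 and raised 0 by more than 1.5 times, a fit of the libraries compared alone lowered 13 and raised 26, and leaving out the libraries that stand apart lowered 1 and raised 34. Replicate numbers show no pairing, since the correlation of replicate differences between groups was -0.682 to 0.753 over 105 pairs of groups (median 0.014, 21 over 0.1). Depth sets the floor of 3 counts at 0.873 to 2.67 CPM in 31 libraries and at 411 CPM in the shallow one. Of simulated 2-fold changes 33% were recovered at 72 h of the 2iL course, 14% at 36 h, where 1 of the 2 libraries is shallow, and 5% in the difference between courses at 72 h, but depth, group size and dispersion were not varied apart.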

Other observations

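The tests of GC content and transcript length and of undifferentiated cells, and the genes of the opening paragraph, were chosen after the results were seen. Single genes known from the hindbrain and from retinoic acid signalling rose late in the 2i course, but no list of such genes was tested. Of 13 tested Hox genes, which set position along the body axis, 5 had risen and 0 fallen at 72 h and 8 had risen and 0 fallen at 84 h, where 2053 of all 11761 genes rose. At 96 h of the 2iL course 0 rose and 4 fell, namely Hoxb9, Hoxc4, Hoxc12 and Hoxc13. Of these only Hoxc13 was among those that rose at 84 h of the 2i course, so the 2 counts cover largely different genes. Hoxc4, Hoxc12 and Hoxc13 were already lower in 2i than in 2iL at 0 h. Neither the Hox family nor its difference between courses was tested as a group. Hoxa2, a gene of the hindbrain, went from 0 counts to at least 26.9-fold higher at 84 h, Hoxa3 to at least 9.66-fold (adjusted p = 0.104 by DESeq2), and Hoxb2 had a ratio of 90.7 (95% counting interval 15.8 to 3633). Egr2, a hindbrain segmentation factor, had a ratio of 128 (95% counting interval 43.4 to 625). Crabp1, which binds retinoic acid in the cell, rose by 7.79 ± 0.40, and Cyp26b1, which degrades it, by 4.42 ± 0.51 (3.33 without 2i 0 h replicate 1 and 7.60 without 2i 0 h replicate 2). The nuclear receptor Nr2f1 rose by 5.10 ± 0.43 (4.38 without 2i 0 h replicate 1 and 6.10 without 2i 0 h replicate 2) and its relative Nr2f2 by 5.46 ± 0.47 (4.83 without 2i 0 h replicate 1 and 6.28 without 2i 0 h replicate 2). Sox21 (5.21 ± 0.51), Id2 (5.60 ± 0.29) and Foxb1 (6.08 ± 0.44, and 5.30 without 2i 0 h replicate 1 and 7.20 without 2i 0 h replicate 2) rose as well. Fgf4, a signal of the early epiblast, fell by 5.17 ± 0.35 on the log2 scale. In the difference between courses at 72 h the change of Crabp1 was lower in the 2iL course (-5.33 ± 0.61), as was that of Sox21 (-7.28 ± 0.78, and -6.52 without 2iL 0 h replicate 1).

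Some genes of the streak and of Wnt signalling, chosen after their values were seen, rose late in the 2i course. At 72 h against 0 h the list of beta-catenin and TCF targets did not pass (adjusted p = 0.84, and 0.91 with an estimated correlation). Nor did primitive streak (adjusted p = 0.060, and 0.31 with an estimated correlation), though it passed with no filter on low counts (0.00415), without 2i 0 h replicate 2 (0.0438) and without 2i 72 h replicate 2 (0.00924). No list but that of caudal genes was tested between 36 and 72 h. Between 36 and 72 h T, the streak gene also called Brachyury, rose by 6.49 ± 0.75 on the log2 scale (9.06 without 2i 36 h replicate 1 and 5.76 without 2i 36 h replicate 2). Wnt3 rose by 3.54 ± 0.56 and Axin2 by 3.08 ± 0.59 (2.41 without 2i 36 h replicate 1 and 4.02 without 2i 36 h replicate 2). Nkx1-2 rose by 4.06 ± 0.41, Tnfrsf19 by 2.59 ± 0.28 and Nanog by 2.20 ± 0.41. Eomes, another streak gene, changed by 0.05 ± 0.55 (adjusted p = 0.96). For Nanog, undifferentiated cells left in the culture as the whole cause are argued against. At 60 h the other 18 naive genes stood at a median of 3.65% of their level at 0 h (bootstrap interval over these genes, not over samples, 2.14 to 8.99). Nanog stood at 20.8% (25.2% and 16.4% in its libraries). Levels of the streak and Wnt genes were not part of this test, so for them it cannot decide. Klf4 at 22.8%, Klf5 at 36.1%, Tet2 at 45.9% and Gbx2 at 1480% lay above that median, and the first bound set, 5.19%, lies inside that interval and was replaced after the result was seen. Cells of a caudal epiblast kind remain open, since 4 of 6 tested genes of a list of 15 caudal genes rose, against 1553 of 11761 genes (one-sided Fisher's exact test, p = 0.0036). Of these 6, 0, 2, 2 and 1 rose without 2i 36 h replicate 1, 2i 36 h replicate 2, 2i 72 h replicate 1 and 2i 72 h replicate 2 in turn.

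Differences between the 2 libraries of a group were shared most by 4 groups, chosen by their loading of at least 0.25 on the first component of these differences, which holds 37.6% of their sum of squares. The libraries that stand apart in them are 2iL 48 h replicate 1, 2iL 84 h replicate 2, 2iL 96 h replicate 1 and 2i 12 h replicate 2. Across 5699 genes the absolute correlation of these differences was 0.289 to 0.753 in the 6 pairs they form (median 0.521), at most 0.287 in the 44 pairs with another group and at most 0.249 in the 55 pairs of other groups, and a higher value among the 4 follows in part from that choice. As the whole cause a difference in depth is argued against by libraries thinned to 1 depth, where the median among the 4 was 0.466. Reads shared with near-identical copies are argued against by genes with no shared 50-mer in the tail (0.509). With a trend on GC content and length of each gene's longest transcript removed the median was 0.522, which argues against these 2 whole-transcript traits. Since the libraries were read from the 3' end, that test cannot decide on the GC content of the reads. Each of the 4 had less of the ribosomal protein genes Rps24 and Rps12 and of Dusp6 than its partner, genes chosen after their values were seen. In 2iL 48 h replicate 1 Rps24 was at 659.9 CPM without TMM factors, against 2948.8 in replicate 2. In 2i 12 h replicate 2 Rps12 was at 1621.6, against 2247.2 in replicate 1. Among the lowest genes of this pattern were the list members Ndufa1, Ndufa4, Dusp6 and Pim3, and among the highest Gm26917 and Mvd. The labels give no batch or date for these libraries, and no biological explanation was tested.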
